A study of Mus musculus with 8 samples.

How the data were processed

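RNA of sorted CD4+ TCRβ+ CD25+ cells was profiled on 8 Affymetrix arrays, 4 from WT chimeras and 4 from IIKO chimeras, grouped by the samples' titles. The deposited values are log2 expression per probe set, made by the authors with affy and RMA per the submitters' processing notes; versions and parameters are not given in the sources used here. RMA corrects background, normalizes the arrays to common quantiles and summarizes the probes of a set. The log2 scale follows from the values themselves, which ran from 2.54 to 13.72 with array medians of 6.96 to 7.03. Probe-level scanner data were not used here, so neither the background nor single probes could be examined. The labels call the samples biological replicates without saying how many mice each one pools, and p-values measure the spread between these samples. The smallest SD of the difference between any 2 arrays over all genes was 0.185, so no array repeated another.

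Probe sets were named from the platform annotation. Of 34760 probe sets, 21640 had 1 gene symbol, 1321 had several and 11799 had none; the last 2 kinds were left out. A mouse reference gene table (assembly GRCm38.p6) was matched by gene identifier for 21553 of them and changed 0 symbols. It was used for names, chromosomes and the order and distance of neighbours, and because the array annotation names no build, no coordinates are given. Where a gene had several probe sets (954 genes), the 1 with the highest mean over all arrays was kept, which left 19937 genes, 19855 of them with a position. No filter on dim genes was applied; the median gene level was 7.10 and the quartiles were 6.04 and 8.53.

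Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over both groups, IIKO minus WT, 6 residual degrees of freedom per gene), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Counts called unadjusted are genes at an unadjusted limma p under 0.05. All tests were two-sided. Gene lists were tested as sets with limma's camera at a preset correlation between genes of 0.01, which asks whether a list is shifted against all other genes; an estimated correlation and fry, which asks whether a list's genes move one way, were alternatives. Each list's mean per array was also compared with an exact permutation test over the 70 labelled splits, whose smallest two-sided p is 0.0286. Placement on chromosomes and near H2-Ab1 (within 10 Mb, or 5 Mb as the alternative) was tested with Fisher's exact test, and neighbouring of changed genes among 20 tested genes on either side with 10000 shuffles of the calls.

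The lists, tests, naming rule and most alternatives were fixed before the data were examined. The 21 lists cover Treg identity, suppressive and effector Treg molecules, TCR-induced genes, TCR signalling machinery, naive-cell and lymph-node homing genes, effector chemokine receptors and adhesion, cell cycle, type I interferon response, the IL-2 and STAT5 pathway, the NF-κB pathway, cell death and survival, T helper cytokines and transcription factors, glycolysis, cholesterol synthesis, MHC class II genes, markers of B and plasma cells, myeloid and dendritic cells, NK and CD8 T cells, erythroid cells and thymocytes, and sex-linked genes (the last not tested as a set). Of their 493 different members, 40 had no probe set with 1 symbol and were not analysed here. The genes named are up to 10 with the largest change in each direction among those past the threshold whose groups do not overlap, without unnamed gene models, small RNAs, antigen receptor segments, pseudogenes and olfactory or vomeronasal receptors; the 3 members of each list with the smallest p (2 for marker and sex-linked lists); and Foxp3, Il2ra, Cd4, Ctla4, Ikzf2, Nr4a1, Egr2, Cd5, Cd69, H2-Ab1, H2-Aa and Cd74.

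Alternatives were a threshold of 0.01, the replicate number as a block, a further quantile normalization, median centring, the brighter 9969 genes alone, eBayes with a trend and robust variance, array weights, the mean of a gene's probe sets, and each array left out in turn. Leaving out the genes of chromosomes 7 and 17 and the exact permutation of list means were added after the data were seen. The fit was tested on simulated arrays of the same 19937 genes, with 200 genes changed, 10 times over. These had the real means, independent normal noise and limma's moderated spreads, shuffled between genes. Moderation draws the spreads of genes together, so recovery in the real data may be lower. The fit recovered 89.3% of genes changed by 0.5 log2, 99.1% of those changed by 1 and 99.8% of those changed by 2, and 4.52% of calls were false. Camera found a simulated list of 25 genes shifted by 0.12 in 10 of 10 runs and called 0 of 190 unchanged lists, in noise without correlation between genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.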

Results

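Gene expression was measured in regulatory T cells (Tregs), the CD4+ T cells that restrain immune responses, taken from bone marrow chimeras. Recipient mice lacked CD3ε, a subunit of the T cell receptor (TCR) complex without which T cells do not form. After lethal irradiation they received marrow from wild-type donors (WT chimeras) or from donors labelled IIKO (IIKO chimeras). The labels describe the Tregs of the IIKO chimeras as cells that lack contact between their TCR and MHC class II in the periphery. At 28 days after reconstitution, CD4+ TCRβ+ CD25+ cells were sorted from lymph nodes and spleen, and 100 ng of total RNA per sample was labelled for 1 Affymetrix array. Each group had 4 biological replicates, and the labels give C57BL/6 mice aged 6 to 8 weeks. The array medians over 34760 probe sets lay between 6.96 and 7.03 on the log2 scale, and the number of arrays limits the precision of every value below.

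The comparison of IIKO with WT chimera Tregs addressed which transcripts of peripheral Tregs differ with the donor marrow. The labels tie IIKO marrow to lost TCR contact with MHC class II in the periphery. Any other effect of the donor marrow, also one on the cells' development, could not be told apart from that loss. The 8 arrays were close to each other. Across the 19937 genes tested, Pearson's r averaged 0.994 over the 6 pairs of WT arrays and 0.995 over the 6 pairs of IIKO arrays. Over the 16 pairs between groups it averaged 0.992; genes are not independent replicates. Foxp3, the transcription factor that defines Tregs, was at 10.63 ± 0.04 in WT and 10.68 ± 0.12 in IIKO chimeras (log2, SD, n = 4 arrays each). Its difference of 0.05 had a 95% confidence interval of -0.10 to 0.19. Il2ra, which encodes the sort marker CD25, was at 12.01 ± 0.04 and 12.18 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.211). Cd4 was at 10.62 ± 0.07 and 10.75 ± 0.07 (adjusted p = 0.289).

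Transcripts of the classical MHC class II chains had lower means in the IIKO chimeras, past the test for 1 of them. The plan did not expect mouse T cells to transcribe these chains, so carried-over cells may be their source, which was not tested. H2-Eb1, the E beta chain, fell from 8.29 ± 0.15 to 7.60 ± 0.10 (SD, n = 4 arrays each), a fall 1.61-fold in size with a limma adjusted p of 0.00746. H2-Aa, the A alpha chain, differed by -0.77 ± 0.21 (log2, SE) and H2-Ab1, the A beta chain, by -0.71 ± 0.24. Neither passed (limma adjusted p = 0.166 and 0.207), with IIKO arrays spread by an SD of 0.52 and 0.56. In IIKO array 3, H2-Aa was at 8.06 and H2-Ab1 at 8.27, within the ranges of the WT arrays (7.99 to 8.30 and 7.87 to 8.39). The mean of the myeloid and dendritic cell markers was also highest in this array, at 6.996, and was lowest in IIKO array 4, at 6.599, where H2-Aa was lowest. IIKO arrays 1 and 2 did not follow that order, with marker means of 6.739 and 6.702 and H2-Aa at 7.26 and 7.55. For H2-Aa and H2-Ab1, the IIKO arrays other than array 3 lay between 6.82 and 7.65. H2-Eb1 in IIKO array 3, at 7.75, stayed below every WT array, and Gdpd3, at 11.67, stood with the other IIKO arrays. Cd74, the invariant chain that loads with class II, went the other way, from 8.88 ± 0.11 to 9.45 ± 0.40 (adjusted p = 0.174). Of the 9 measured class II genes, 1 fell and 8 did not pass. Adjusted over the list alone, H2-Eb1, H2-Aa and H2-Ab1 were lower and Cd74 was higher. The list as a set did not pass (camera, mean -0.22, adjusted p = 0.148), but it did when IIKO array 3 was left out (adjusted p = 0.0278). With an estimated correlation and all arrays its adjusted p was 0.467. Cd74 passed when IIKO array 4 was left out (limma adjusted p = 0.00589). The labels do not name the class II gene disrupted in the donors, so a probe set may lie outside the deleted part.

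Gene by gene, 57 of the 19937 genes changed between the groups. Of these, 32 were higher and 25 lower in IIKO chimera Tregs, and 11 differed at least 2-fold. The largest rise was of Gdpd3, a glycerophosphodiester phosphodiesterase, from 5.83 ± 0.38 to 11.94 ± 0.21 (6.11 log2, limma adjusted p = 5.26e-08; SD, n = 4 arrays each). The largest falls were of the TRIM family genes Trim30d, from 10.30 ± 0.19 to 5.87 ± 0.35 (-4.43 log2, adjusted p = 3.42e-07), and Trim12a, from 10.02 ± 0.06 to 6.22 ± 0.22 (-3.80 log2, adjusted p = 4.74e-08). Gdpd3 in WT and Trim30d in IIKO chimeras lay below the lower quartile of gene levels (6.04), and background was not examined, so the sizes of these differences, as log2 or as folds, depend on a level that was not checked.

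Further rises were of Trim12c (1.43 log2), Dnah8, an axonemal dynein heavy chain (1.42), and Ppp1r11, an inhibitor of protein phosphatase 1 (1.13). Smaller rises were of Btnl2, a butyrophilin-like membrane protein (0.87), Prelid2 (0.86), Trim34a (0.83), Glo1, the glyoxalase that detoxifies methylglyoxal (0.83), Ccdc88a, an actin-binding protein (0.82), and Gabbr1, a GABA-B receptor subunit (0.74). Further falls were of Ccnyl1 (-1.11), Ccr9, the receptor for the gut and thymus chemokine Ccl25 (-1.06), Cln3, a lysosomal membrane protein (-1.0), Zfp948 (-0.98) and Dnajb13 (-0.96). Smaller falls were of Alg8, a glucosyltransferase of N-glycan assembly (-0.92), Thrb, the thyroid hormone receptor beta (-0.88), and Lrrc32, which encodes GARP, the Treg surface protein that holds latent TGF-β (-0.74). Limma adjusted p values of these 17 genes ran from 0.000112 for Dnah8 to 0.0464 for Ccdc88a. Ccr9 was at 8.43 ± 0.33 in WT and 7.37 ± 0.05 in IIKO chimeras (2.09-fold lower, adjusted p = 0.011). Lrrc32 was at 9.07 ± 0.15 and 8.33 ± 0.24 (1.67-fold lower, adjusted p = 0.0373; SD, n = 4 arrays each).

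The changed genes were unevenly placed in the genome. Chromosome 7 held 17 of them, 7 higher and 10 lower, against 8.73% of all genes with a position (Fisher's exact test, two-sided, odds ratio 4.48, adjusted p = 4.59e-05 over the chromosomes). Chromosome 17, which carries the MHC, held 18, 11 higher and 7 lower (odds ratio 9.49, adjusted p = 1.29e-09). On chromosome 7 lay Gdpd3, Trim12a, Trim12c, Trim30d, Trim34a, Cln3, Dnajb13, Alg8 and Lrrc32. On chromosome 17 lay Dnah8, Ppp1r11, Btnl2, Glo1, Gabbr1, Zfp948 and H2-Eb1. Within 10 Mb of H2-Ab1 there were 12 changed genes, 21.1% of the 57, against 2.24% of all tested genes (Fisher's exact test, two-sided, odds ratio 11.9, p = 3.94e-09). In gene order, 28 of the 57 had another changed gene among the nearest 20 tested genes on either side, against a mean of 6.00 in 10000 shuffles (permutation p = 1e-04, the smallest these shuffles can give). Outside chromosomes 7 and 17, 0 of 22 had such a neighbour, against a mean of 1.01 (permutation p = 1).

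**Figure D1:**
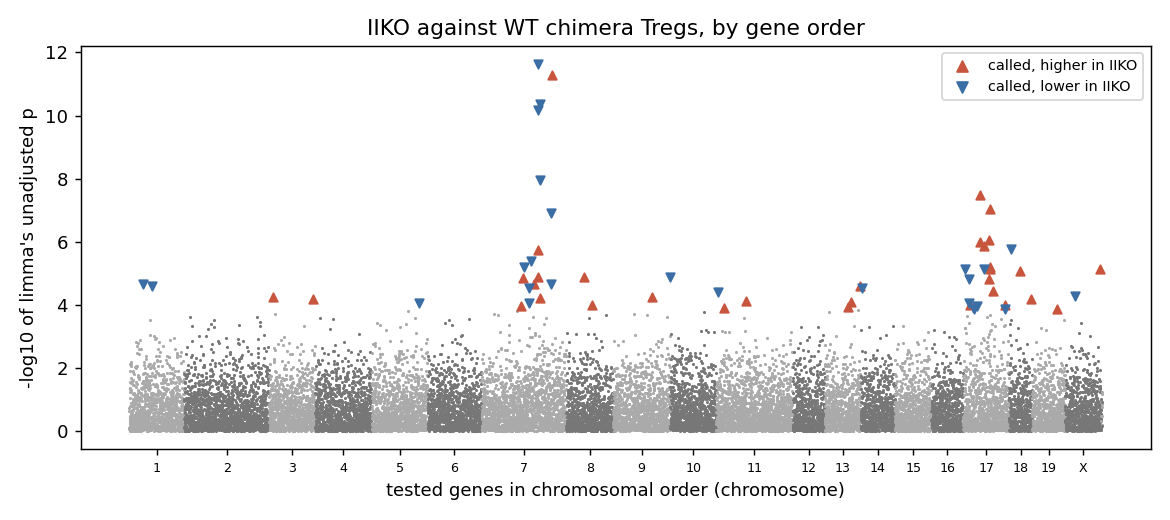
Unadjusted limma p of each tested gene (−log10, vertical axis) against its place in chromosomal order (horizontal axis, numbered by chromosome), for IIKO against WT chimera Tregs, 4 arrays each. Triangles are the 57 genes past an adjusted p of 0.05, pointing up where higher in IIKO (32) and down where lower (25), and 35 of them stand on chromosomes 7 and 17.

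With the genes of chromosomes 7 and 17 left out of the test, a check chosen after their share was seen, 5 of 17267 genes passed. Higher in the IIKO chimeras were Prelid2 (0.86), Ap1s2, an adaptor protein of vesicle transport (0.68), and Zfp868 (0.65), and lower were Ccr9 (-1.06) and Npc1, the lysosomal cholesterol transporter (-0.73). Their limma adjusted p lay between 0.0306 and 0.0483. No genotype was used here, so donor differences near these genes were not tested. Ap1s2, Zfp868 and Npc1 were named after their values were seen. Of all 57 genes, 27 passed whichever array was left out, and 22 of these 27 lie on chromosomes 7 or 17. The count fell from 57 to 32 without WT array 1 or IIKO array 2, 33 without WT array 3, 35 without IIKO array 3 and 36 without IIKO array 1. Ccr9 passed each time, while Lrrc32 did not pass without WT arrays 1, 2 or 3 or IIKO arrays 1, 2 or 4 (limma adjusted p from 0.0788 to 0.11). Alg8 did not pass without WT arrays 1, 2 or 3 or IIKO arrays 2, 3 or 4 (0.0600 to 0.0750), nor Thrb without WT arrays 1 or 4 or IIKO arrays 2 or 3 (0.0526 to 0.0710). Ccnyl1 did not pass without IIKO arrays 2, 3 or 4 (0.0528 to 0.0637). Ccdc88a did not pass without any array except WT array 1 (0.0685 to 0.135), after a further quantile normalization (0.0532) or with arrays centred on their medians (0.0502). With the replicate number as a block, though these numbers did not pair the arrays, Ccnyl1 (0.0696), Ccdc88a (0.1285), Prelid2 and Gabbr1 (0.05065 each) did not pass.

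Of the 34 measured genes of the Treg identity list, 33 did not pass the test and 1 fell, Lrrc32, which lies on chromosome 7 among the changed genes there. At an unadjusted limma p under 0.05, 4 of the 34 were higher and 3 lower. Of all genes tested, 17.3% lay under it. Ctla4, the inhibitory receptor of Tregs, was at 12.24 ± 0.06 and 12.36 ± 0.04 (SD, n = 4 arrays each; limma adjusted p = 0.272). Ikzf2, which encodes Helios, was at 12.06 ± 0.03 and 12.11 ± 0.02 (adjusted p = 0.634). Adjusted over the list alone, Nrn1, which encodes neuritin (0.65 ± 0.14, SE), was higher. On that scale Lrrc32 and the tetraspanin gene Cd81 (-0.27 ± 0.07), also on chromosome 7, were lower. The list did not pass as a set (camera, mean 0.0063, adjusted p = 0.088; 0.528 with an estimated correlation), and its mean turned to -0.021 after a further quantile normalization of the arrays. It passed camera without WT array 3 (adjusted p = 0.0405), without IIKO array 4 (0.0159) and without the genes of chromosomes 7 and 17 (0.00976, but adjusted p = 0.491 with an estimated correlation).

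Among suppressive and effector Treg molecules, 1 of the 32 measured genes fell (Lrrc32) and 31 did not pass. Adjusted over the list alone, Il10, the suppressive cytokine (0.52 ± 0.13, SE), Irf4, a transcription factor of effector Tregs (0.26 ± 0.07), and Lag3, an inhibitory receptor, were higher and Lrrc32 was lower. The list lay above the other genes by camera (mean 0.029, adjusted p = 0.0156), a call lost with an estimated correlation (adjusted p = 0.489), and its mean was -0.00048 after a further quantile normalization. The call was also lost without WT array 2 (adjusted p = 0.0962), IIKO array 1 (0.0726) or IIKO array 2 (0.208), after the further quantile normalization (0.0712) and among the brighter genes (0.432).

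Genes that TCR signals induce showed no rise or fall past limma's test. Of the 45 measured members of the TCR-induced list, 0 passed, with 23 positive and 22 negative differences, and at an unadjusted p under 0.05, 6 were higher and 3 lower. Nr4a1, the immediate early gene whose level follows TCR signal strength, was at 8.52 ± 0.12 in WT and 8.53 ± 0.11 in IIKO chimeras (SD, n = 4 arrays each), a difference of 0.01 that turned to -0.03 after a further quantile normalization. Its 95% confidence interval was -0.16 to 0.18. Egr2 differed by 0.10 ± 0.09 (SE), Cd69, an early activation marker, by 0.11 ± 0.09 (limma adjusted p = 0.606 and 0.537). Cd5, a surface protein set by TCR signal strength, differed by -0.06 ± 0.06 (adjusted p = 0.612). Bhlhe40, a transcription factor of activated T cells (0.65 ± 0.14, SE), was higher and Ier3 (-0.41 ± 0.10), a survival gene on chromosome 17, was lower when adjusted over the list alone. The set had a mean of 0.013, turning to -0.014 after a further quantile normalization, and did not pass (camera adjusted p = 0.0734; 0.489 with an estimated correlation). It passed without WT array 1 (adjusted p = 0.0169), WT array 2 (0.0402) or IIKO array 4 (0.0159).

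The TCR signalling machinery, the proteins that carry the signal, had 40 measured genes and 0 that passed, over all genes or adjusted over the list alone. At an unadjusted limma p under 0.05, 3 were higher: Themis (0.39 ± 0.12, SE), Sos1 (0.22 ± 0.07) and Malt1 (0.41 ± 0.13). Its mean was 0.028 (camera adjusted p = 0.0236; adjusted p = 0.215 with an estimated correlation), -0.0027 after a further quantile normalization. It did not pass without IIKO array 3 (adjusted p = 0.0682), without the genes of chromosomes 7 and 17 (0.128), after the further quantile normalization (0.307) or among the brighter genes (0.7605).

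**Figure D2:**
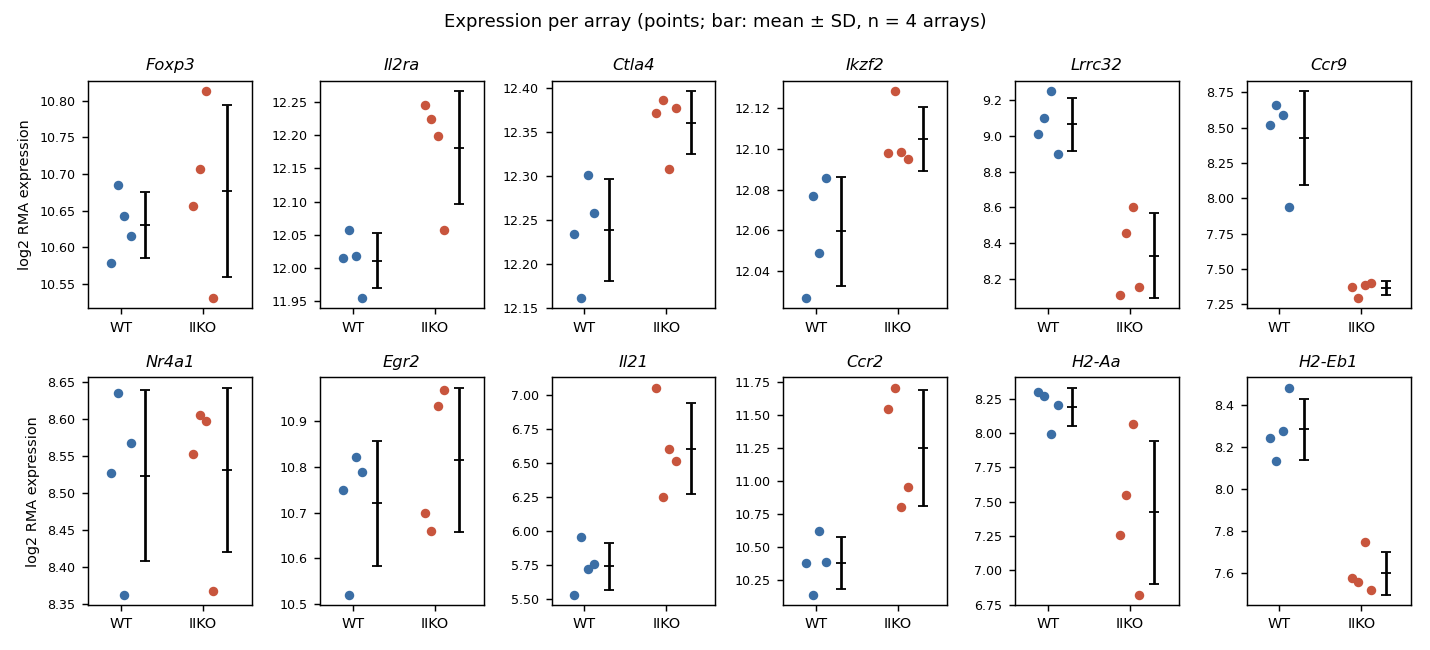
Log2 RMA expression (vertical axis, scaled per gene) of 12 genes in WT (blue) and IIKO (red) chimera Tregs; points are arrays, bars the mean ± SD of 4 arrays. Foxp3, Nr4a1 and Egr2 overlap between the groups, while Lrrc32, Ccr9 and H2-Eb1 are lower in all 4 IIKO arrays and passed limma's adjusted p of 0.05.

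Genes of naive cells and lymph node homing had 1 fall, of Ccr9, among 28 measured genes, and 27 did not pass. Ccr9 was also the 1 gene that passed adjusted over the list alone. Pecam1 differed by 0.26 ± 0.09 (SE) and Foxo1, the transcription factor that sustains homing receptors, by -0.17 ± 0.06 (limma adjusted p = 0.212 and 0.235). The list's mean was -0.031 and its median 0.051. Camera placed it upward and fry downward, with neither past its threshold (camera adjusted p = 0.27; fry adjusted p = 0.919). Effector chemokine receptors and adhesion molecules had 0 of 27 genes past limma's test (7 at an unadjusted p under 0.05). Ccr2, the receptor for Ccl2, on chromosome 9 like Ccr9, was higher adjusted over the list alone (0.87 ± 0.19, limma adjusted p = 0.116 over all genes). That list did not pass camera (mean 0.051, adjusted p = 0.0774; 0.489 with an estimated correlation) but did without WT array 1 (0.0461), WT array 3 (0.0405) or IIKO array 3 (0.0174).

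Of the 20 lists tested as sets, 8 lay above the other genes by camera with a preset correlation, and 0 did with an estimated correlation, where the lowest adjusted p was 0.215 and 3 lists had an unadjusted p under 0.05. Estimating the correlation also lowers the degrees of freedom of camera. With each list's own estimated correlation and the degrees of freedom kept, a check chosen after the results were seen, 2 passed: the helper T cell list (adjusted p = 0.0259) and the IL-2 and STAT5 list (0.0312). Among the brighter genes alone, 7 of the 8 did not pass (adjusted p from 0.0775 for the interferon list to 0.7605 for the TCR machinery). Below 0 lay 46.4% of the brighter 9969 genes and 79.5% of the dimmer 9968. An unadjusted limma p under 0.05 was found for 17.3% of all genes. The NF-κB pathway list stood highest, with 20 of 21 genes positive, among them Nfkb2 (0.22 ± 0.07, SE), Traf1 (0.24 ± 0.09) and Traf2 (0.17 ± 0.07), and 0 past limma's test (3 at an unadjusted p under 0.05). Its mean was 0.12 (camera adjusted p = 6.04e-06; adjusted p = 0.215 with an estimated correlation). Type I interferon response genes had 26 of 32 positive, including Xaf1 (0.30 ± 0.10), Ddx58 (0.19 ± 0.07) and Oas3 (0.21 ± 0.08), with 0 past limma's test (6 at an unadjusted p under 0.05). The interferon list had a mean of 0.12 (camera adjusted p = 2.47e-05; adjusted p = 0.489 with an estimated correlation). Genes of the IL-2 and STAT5 pathway had 15 of 20 positive, led by Il2 (0.44 ± 0.11), Dusp6 (0.24 ± 0.08) and Il2ra (0.17 ± 0.06), with 0 past limma's test (4 unadjusted). The IL-2 list had a mean of 0.084 (camera adjusted p = 0.00435; adjusted p = 0.215 with an estimated correlation).

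Helper T cell cytokines and transcription factors had 0 of 31 genes past limma's test over all genes (8 unadjusted). Adjusted over the list alone, Il21, a cytokine of follicular helper cells (0.87 ± 0.15, SE), Il2 and Stat4 (0.36 ± 0.10) were higher. Both Il2 and Il21 lie on chromosome 3. The helper T cell list had a mean of 0.082 (camera adjusted p = 0.00755; adjusted p = 0.215 with an estimated correlation). Il21 was at 5.74 ± 0.17 in WT and 6.60 ± 0.34 in IIKO chimeras, below the median level of 7.10 over all genes in both (SD, n = 4 arrays each; limma adjusted p = 0.0585). It passed without IIKO array 2 (adjusted p = 0.038) and after a further quantile normalization (0.046). Glycolysis genes had 17 of 19 positive, among them Pdk1 (0.25 ± 0.10), Tpi1 (0.18 ± 0.10) and Pfkl (0.10 ± 0.07), with 0 past limma's test (1 unadjusted). The glycolysis list had a mean of 0.075 (camera adjusted p = 0.00427; adjusted p = 0.215 with an estimated correlation). Cholesterol synthesis genes had 14 of 19 positive, among them Stard4 (0.35 ± 0.11), Sqle (0.27 ± 0.13) and Idi1 (0.38 ± 0.19), with 0 past limma's test (1 unadjusted). The cholesterol list had a mean of 0.072 (camera adjusted p = 0.0236; adjusted p = 0.489 with an estimated correlation). A second probe set of Idi1, dimmer than the one used, differed by -0.54. The cholesterol call was lost without WT array 4 (adjusted p = 0.424), IIKO array 1 (0.0834) or IIKO array 2 (0.115), after a further quantile normalization (0.0791), with a gene's probe sets averaged (0.0601) and among the brighter genes (0.483).

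Cell cycle genes had 0 of 44 past limma's test (7 unadjusted), among them Birc5 (-0.20 ± 0.06, SE), Ccne1 (-0.34 ± 0.12) and Ndc80 (0.24 ± 0.09). Their mean was -0.035 and their median -0.024, while camera placed them upward (adjusted p = 0.817). Cell death and survival genes had 0 of 22 past limma's test (3 unadjusted), among them Tnfrsf10b (0.26 ± 0.11), Bik (-0.14 ± 0.06) and Mcl1 (0.12 ± 0.05). Their mean of -0.016, which turned to 0.0019 with each array centred on its median, also lay below 0 where camera placed them upward (adjusted p = 0.584).

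**Figure D3:**
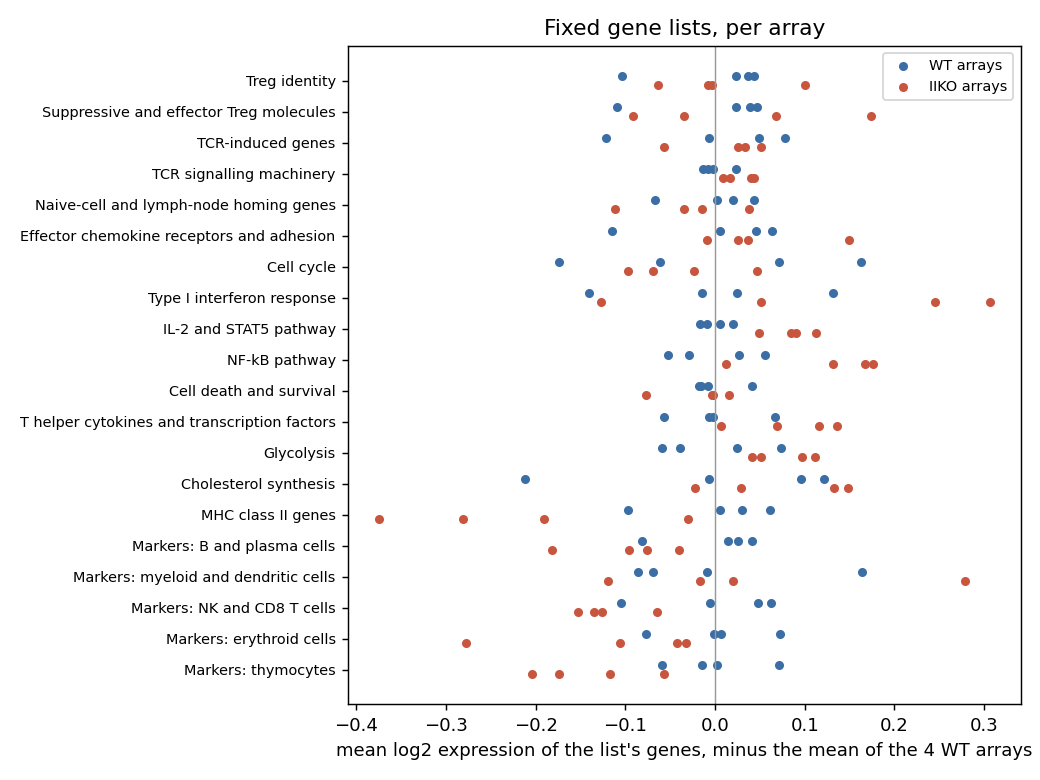
Mean log2 expression of each fixed gene list per array (horizontal axis, minus the mean of the 4 WT arrays), with WT arrays in blue and IIKO arrays in red. The IL-2 and STAT5 list is the 1 of 20 whose arrays do not overlap between groups (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 arrays can give; adjusted p = 0.214).

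Markers of other cell types that a sort could carry along held 1 gene past limma's test, Ccr9. Above the median gene level lay 3 of 18 B and plasma cell markers, 5 of 21 myeloid and 4 of 13 NK and CD8 T cell markers. B and plasma cell markers had a mean of -0.098 over 18 genes, with 0 past limma's test (3 unadjusted), among them Vpreb3 (-0.29 ± 0.12, SE) and Fcer2a (-0.26 ± 0.09). Their camera adjusted p was 0.17 (0.489 with an estimated correlation), and 0.0475 without WT array 2. Myeloid and dendritic cell markers had a mean of 0.041 over 21 genes, with 0 past limma's test (2 unadjusted), among them Siglech (-0.19 ± 0.06) and S100a8 (-0.33 ± 0.12; camera adjusted p = 0.233). The mean difference turned to -0.038 without IIKO array 3, and the list passed camera without WT array 4 (adjusted p = 0.0497) or IIKO array 4 (0.0438). With an estimated correlation and all arrays its camera adjusted p was 0.627. NK and CD8 T cell markers had a mean of -0.12 over 13 genes, with 0 past limma's test (5 unadjusted; camera adjusted p = 0.279; fry, downward, adjusted p = 0.0103). Nkg7, a cytotoxic granule protein on chromosome 7, was lower adjusted over the list alone (-0.35 ± 0.07, limma adjusted p = 0.0847 over all genes; 0.0490 with a trended and robust eBayes fit), and Klri2 differed by 0.23 ± 0.07. Erythroid markers had a mean of -0.11 over 8 genes, with 0 past limma's test (1 unadjusted), Slc4a1 at -0.19 ± 0.08 and Ermap at -0.19 ± 0.09 (camera adjusted p = 0.279). Thymocyte markers had a mean of -0.14 over 11 genes, of which Ccr9 fell (camera adjusted p = 0.364). Ccr9 and Sox4 (-0.24 ± 0.06) were lower and Themis higher adjusted over the list alone. Of 4 sex-linked genes, 0 separated the groups. Kdm5d was at 9.65 ± 0.11 and 9.51 ± 0.14 and Eif2s3y at 9.49 ± 0.20 and 9.66 ± 0.14 in WT and IIKO chimeras (SD, n = 4 arrays each).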

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

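Of the tests below, those on the chromosome 7 genes, on NK and CD8 T cells, on correlation, on bright and dim genes, on single arrays and on the splits of all counts except the total were chosen after the results were seen.

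In 13 of 202 groups of 4 arrays, 1 array stood far from the other 3, by Dixon's criterion of the gap to the nearest array over the group's range; chance alone does this in about 5% of groups, or 10.1 of 202. Ccdc88a in IIKO array 2 was at 7.63, above the others at 7.41 to 7.44, and Dnajb13 in WT array 4 was at 8.56, below 8.67 to 8.69. Il10 in IIKO array 3 was at 9.36, below 9.63 to 9.65. Ier3 in WT array 4 was at 6.97, below 7.16 to 7.19. Traf1 in IIKO array 4 was at 9.75, below 10.08 to 10.14. Pdk1 in WT array 1 was at 8.21, below 8.51 to 8.55, and Stard4 in the same array was at 9.02, above 8.58 to 8.65. Sqle in WT array 4 was at 7.77, below 8.24 to 8.33. Vpreb3 in IIKO array 1 was at 6.44, below 6.70 to 6.73. Ikzf2 in IIKO array 2 was at 12.13, above 12.09 to 12.10. H2-Ab1 in WT array 2 was at 7.87, below 8.30 to 8.39. In that array the mean of the Treg identity list was 10.13, below 10.26 to 10.28, and the mean of the suppressive and effector list was 9.88, below 10.01 to 10.03.

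The 57 changed genes exceeded what other groupings gave: 1 of the 35 splits of the 8 arrays into 4 and 4 gave as many, the real one, and the highest other split gave 1 (the parts of the total, 32 in the larger direction, 25 in the smaller, 11 at least 2-fold and 12 within 10 Mb of H2-Ab1, could then reach at most 1 elsewhere and add no support). A different share of B, plasma, myeloid, NK or CD8 T cells is only weakly argued against for the set as a whole. B and plasma cell markers had a camera adjusted p of 0.170 and a median of -0.10, myeloid markers 0.233 and 0.02, and NK and CD8 T cell markers 0.279 and -0.10. The median size of the 57 changes was 0.67. Most of these markers lay below the median gene level, which weakens the check, and the purity of the sort was not measured here. Conventional CD4 T cells that carry CD25 would pass the same sort. Their share was not tested and stays open. A different donor sex is argued against because 0 of 4 Xist and Y-linked genes separated the groups. The 4 NK and CD8 T cell markers above the median gene level had a median of -0.40, so a lower share of these cells stays open for single falls, though not for the 32 rises. A candidate explanation for the 12 genes near H2-Ab1 is donor strain variants carried along with the disrupted class II locus: they were 21.1% of all changes, above the 10% set in advance. It is open whether such variants would alter the transcripts or the binding of probes, and an effect of lost class II contact on single genes there stays open too.

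The gathering of 17 changes on chromosome 7 may come from a second segment in which the donors differ, since the 603 genes not called between the outermost calls, Slco3a1 and Gdpd3, had an unadjusted p under 0.05 more often than uncalled genes off chromosomes 7 and 17 (24.7% against 16.6%, odds ratio 1.65, Fisher p = 5.59e-07; 1.68 when compared among genes of like level), and those on the rest of chromosome 7 had an odds ratio of 1.06 (p = 0.455). The stretch was bounded by the calls themselves and nearby genes can vary together, so this supports a local difference without naming its source. An interferon response, which could act on TRIM genes, was not settled. Trim12a and Trim30d fell by at least 3.50 log2 more than any gene of the interferon list, whose mean was above 0. They were the largest falls among the changed genes, so that comparison was bound to hold and excludes nothing. Trim12c (1.43) and Trim34a (0.83), also on chromosome 7, rose in the direction of that mean. The labels give C57BL/6 mice without stating the background of the IIKO donors, and no genotype was used here. If donors differed over this stretch, the fall of Lrrc32, which also lies on chromosome 7, could be a donor difference and not a response to class II. Only donors matched over this stretch would separate these.

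The 8 lists that passed camera with a preset correlation cannot be set apart from other groupings: 6 of the 35 splits gave 8 or more lists, and the highest other split gave 11. Whether correlation between the genes of a list accounts for the calls could not be told for the 8 lists together. With each list's own estimated correlation and the degrees of freedom of the test kept, 2 of the 8 passed, the helper T cell list and the IL-2 and STAT5 list. That check treats an estimated correlation as known. For the helper T cell list the estimate (0.0071) lay below the preset 0.01, so its pass adds little. For the interferon, cholesterol and suppressive lists the estimates were far above it (0.592, 0.296 and 0.225). With these and the degrees of freedom kept, each had a camera adjusted p of 0.425, so their calls rested on the preset correlation. With camera's own handling of an estimated correlation 0 lists passed. An offset between bright and dim genes may also contribute: the median difference was 0.01 in the brighter 9969 genes and -0.07 in the dimmer 9968, and 1 list, the NF-κB pathway, passed when tested among the brighter genes. At least 6 lists passed whichever array was left out, so the count did not hang on 1 array. Which lists passed did change: 5 of the 8 passed each time. A small shift of the NF-κB pathway with lost class II contact stays open, as a hypothesis that these arrays did not settle. Its list did not pass camera with an estimated correlation (adjusted p = 0.215). Nor did it pass with its own correlation and the degrees of freedom kept (camera adjusted p = 0.0510).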

How the results depend on the processing

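Leaving out chromosomes 7 and 17, the exact permutation of list means and each list's own correlation with the degrees of freedom kept were chosen after seeing the data; causes were not tested beyond what a setting removes. The share of changed genes near H2-Ab1 passed under every alternative that kept chromosome 17 (15.8% to 38.1%). At a threshold of 0.01, 21 genes passed (11 higher, 10 lower) with 5 lists. The suppressive list (mean 0.029, camera adjusted p = 0.0156) did not. Replicate numbers did not pair the arrays (correlations of deviations 0.045, -0.015, -0.068 and 0.220; 2 of 8 arrays resembled their own number most); with the replicate block 31 genes passed (15 higher, 16 lower), 28 of them among the 57, and 8 lists. After a further quantile normalization 60 genes passed, 52 shared, with 5 lists, and the mean turned to -0.021 for Treg identity, -0.00048 for suppressive molecules, -0.014 for TCR-induced genes and -0.0027 for TCR machinery, and Nr4a1 to -0.031. Median centring turned cell death to 0.0019, and averaging probe sets turned Idi1 to -0.077. In the brighter 9969 genes 1 list passed and suppressive molecules (mean 0.037, camera adjusted p = 0.432) did not. With array weights TCR-induced genes did (mean 0.022, camera adjusted p = 0.0440). With an estimated correlation 0 lists passed (suppressive molecules: mean 0.029, camera adjusted p = 0.489). By fry 1 passed (NK and CD8 markers, downward), by exact permutation 0, with own correlations and the degrees of freedom kept 2. Without chromosomes 7 and 17, 5 genes passed (3 higher, 2 lower, 1 at least 2-fold). So did Treg identity (mean 0.047, camera adjusted p = 0.00976, but 0.491 with an estimated correlation). Leaving out 1 array gave 32 to 50 changed genes (17 to 26 higher, 14 to 25 lower), and means of -0.028 to 0.029 for Treg identity, -0.019 to 0.069 for suppressive molecules, -0.027 to 0.040 for TCR-induced genes, -0.093 to 0.019 for cell cycle, -0.027 to 0.0035 for cell death and -0.038 to 0.095 for myeloid markers, and Nr4a1 at -0.046 to 0.062. Background was not examined, and genes near the lower quartile of signal (6.04) may lie at it, among them Gdpd3 (5.83), Il2 (6.01) and Il21 (5.74) in WT and Trim30d (5.87) and Thrb (5.79) in IIKO arrays.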

Other observations

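The count of splits and the mixed test in this part were chosen after the results were seen.

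Beyond the genes past the threshold, 3446 genes (17.3% of those tested) had an unadjusted limma p under 0.05, where 997 would do so by chance. In 1 of the 35 splits of the arrays, the real one, as many did, and the highest other split gave 2210. Without the genes of chromosomes 7 and 17 the share was 16.7%, so the excess was not confined to these chromosomes. An offset between bright and dim genes may contribute to the excess, which was not tested. Most genes of the dimmer 9968 (79.5%) lay below 0, against 46.4% of the brighter 9969.

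By fry's mixed test, which asks whether genes of a list change in either direction, 10 of the 20 lists passed. The test is against no change, and with 17.3% of all genes at an unadjusted p under 0.05 a pass does not set a list apart from other genes. NK and CD8 T cell markers were the 1 list that passed fry in 1 direction, downward (adjusted p = 0.0103), but fry tests against no change and 9 of these 13 genes lay in the dimmer set that was mostly below 0. Of the 13, 10 were negative where the shares by brightness give 9.01, and camera did not place them apart from other genes (adjusted p = 0.279). Of the chromosome 7 TRIM genes, Trim30a, a close relative of Trim30d, differed by -0.02.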
